A study of Homo sapiens with 12 samples.

How the data were processed

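RNA-seq was carried out on MCF7 cells, an established breast cancer cell line, kept in DMEM with fetal bovine serum and treated for 6 days with DMSO, tamoxifen, fulvestrant or H3B-5942, each compound at 100 nM, with medium and compound renewed after 3 days. Per the labels, RNA was extracted with Trizol and non-stranded libraries of polyadenylated RNA were built, so transcripts of opposite strands that overlap were not separated. The submitters name kallisto with the genome build hg19, and the version of kallisto and the transcript annotation are not given. There were 12 libraries in 4 groups of 3, with 1 deposited table per library.

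Each deposited table held 20473 genes with a length and an effective length (other, in bases), expected counts and tpm. The authors' expected counts (est_counts) are estimated by kallisto and summed per gene, and 36.5% of them were whole numbers within a tolerance of 1e-06. The authors' tpm values are transcripts per 1000000 over the genes in the table. Library totals ran from 29326783 to 63554957 estimated counts, and a 95% interval of a log2 fold change reached 0.13 to either side in the median gene. The tables give symbols without coordinates, and the annotation at hand (GENCODE 29 on GRCh38) differs from the build of the study, so no positions are given. It matched 19012 genes (92.9%) by symbol, 95.6% of them protein coding, and gave a GC content for 14796 of the tested genes (93.9%).

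Estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 15753, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 12 libraries with a term for each group, leaving 8 residual degrees of freedom, and 6 contrasts were tested with quasi-likelihood F tests (two-sided). P-values were adjusted by the Benjamini-Hochberg method over the 15753 genes of a contrast, with a threshold of 0.05. CPM values use the TMM-scaled totals. The biological coefficient of variation was 3.88%. Replicates differed by more than counting noise, with a chi-square per gene of 2.06 to 9.23 between pairs of libraries of a group.

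Before the data were examined, 21 lists of genes were fixed from textbook knowledge, with 419 memberships, of which 2 are not in the tables. They cover estrogen-induced and estrogen-repressed genes, mitosis, DNA replication, growth arrest, p53 targets, the BCL2 family, cholesterol and fatty acid synthesis, hypoxia and glycolysis, ER stress and ATF4, lysosome, ribosome biogenesis, interferon response, growth factor signalling, drug metabolism, luminal identity, basal, stromal and blood cell markers and mitochondrially encoded genes. Some genes stand in several lists, such as BIK and BMF (estrogen-repressed genes and BCL2 family) and CDKN1A (growth arrest and p53 targets). Lists were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 21 lists of a contrast. Camera with an estimated correlation was run beside it, and so was fry, which asks whether a list's own genes move, on balance, one way. The rule for named genes was fixed at the same time. It takes ESR1, for each compound against DMSO the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and libraries that do not overlap, and up to 4 members per list by smallest adjusted p. Between compounds it takes 5 in each direction and up to 2 per list. Names of clones were left out, and exceptions are said to be chosen after their values were seen.

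Overlaps of the responses were compared with the product of list sizes over genes tested and with 20 simulations of unchanged groups. In these all 12 libraries, DMSO included, were drawn around the DMSO means, and the unchanged groups shared the simulated DMSO libraries. Where a group held 1 to 3 counts in a library, a ratio of pooled counts with an exact binomial 95% interval is given in place of a fitted fold, and 3 counts were taken as the most that a count of 0 allows. Such intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Differences between list scores, the mean log2 CPM over members in a library, are given with 95% intervals from a linear model over the 12 libraries.

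The procedure was tested on simulated data at the depths and spread of these libraries. It recovered 47.8% to 65.7% of 1.2-fold changes, 77.6% to 88.1% of 1.5-fold changes and 86.4% to 92.4% of 2-fold changes, and 4.29% to 9.43% of its calls were false. Only 66 or 67 of 15753 genes were changed at each size, whereas 20.7% to 73.0% of genes were called in the real comparisons. The adjusted threshold depends on that share, so these rates may not carry over. The 1 list changed was called, as was 1 of the 20 left unchanged.

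Alternatives fixed before the data were examined were DESeq2 1.42.0 and limma-voom in place of edgeR, DESeq2 size factors or library totals in place of TMM, no filter or a mean of at least 5 CPM, the 2 compared groups alone, the replicate number as a block, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a test for a change of more than 1.5-fold (glmTreat) and each library left out in turn. Counts thinned to the lowest total, removal of each library's trend with GC content and length, effective lengths as offsets, and another DMSO library for each compound in the correlations were added after the data had been seen. No library was left out of the main analysis, and no deposited sample outside the 4 groups was found. The series title names estradiol, for which there is no sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.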

Results

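RNA was sequenced from MCF7 cells, a human breast cancer line that expresses the estrogen receptor, after 6 days with the vehicle DMSO or with 100 nM of tamoxifen, fulvestrant or H3B-5942. Medium and compound were renewed after 3 days, and each treatment had 3 libraries, 12 in all. Tamoxifen is a selective estrogen receptor modulator and fulvestrant is an estrogen receptor antagonist that also lowers the receptor protein, while H3B-5942 is given by its code name in the labels. The comparisons with DMSO ask how each compound changes gene expression in these cells, and those between compounds ask how their effects differ at the same dose and time. The deposited tables gave estimated counts for 20473 genes per library. Totals ran from 43629162 to 63554957 estimated counts in DMSO, 29326783 to 41731788 in tamoxifen, 34129477 to 44943663 in fulvestrant and 37616673 to 45837652 in H3B-5942. Levels below are CPM (counts per 1000000 counts) as mean ± SD over the 3 libraries of a group, and log2 fold changes are given ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values. Lists of genes were fixed before the data were examined and tested with camera at a preset correlation. Some lists share members, so their results are not independent. A list call given with 1 p-value also passed with an estimated correlation, but its p-value was then larger. For the cell division, estrogen-induced and interferon response lists it was larger by many orders of magnitude, so the preset p-values overstate their evidence. Counts of members adjusted over the list alone equal those over all genes unless given. Nothing in the labels says that the 3 libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

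Pearson's r of log2 CPM across genes was 0.993 to 0.996 within groups and 0.942 to 0.993 between groups. No batch is named in the labels, but the 3 H3B-5942 libraries lie outside the run of library numbers of the other 9, so no value within a batch can be had for H3B-5942, and batch and compound cannot be told apart in its difference from tamoxifen. Its differences from DMSO and from fulvestrant went with those of tamoxifen, whose libraries lie in that run (Pearson's r across genes 0.88 to 0.89 and 0.68 to 0.79, with separate control libraries, a form chosen after seeing the data). The leading principal component held 60.7% of the variance and the second 20.1%. Transcripts encoded by the mitochondrial genome took 5.56% to 5.68% of counts in the DMSO libraries and 4.30% to 4.67% in the 9 treated libraries. ESR1, which encodes estrogen receptor alpha, stood at 471 ± 2.39 CPM in DMSO and was lower under each compound, at 296 ± 3.53 CPM in tamoxifen, 251 ± 3.93 CPM in fulvestrant and 303 ± 6.74 CPM in H3B-5942. Its log2 fold changes were -0.67 ± 0.035 (adjusted p = 9.67e-18), -0.91 ± 0.035 (adjusted p = 1.57e-21) and -0.64 ± 0.034 (adjusted p = 3.00e-17).

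**Figure D1:**
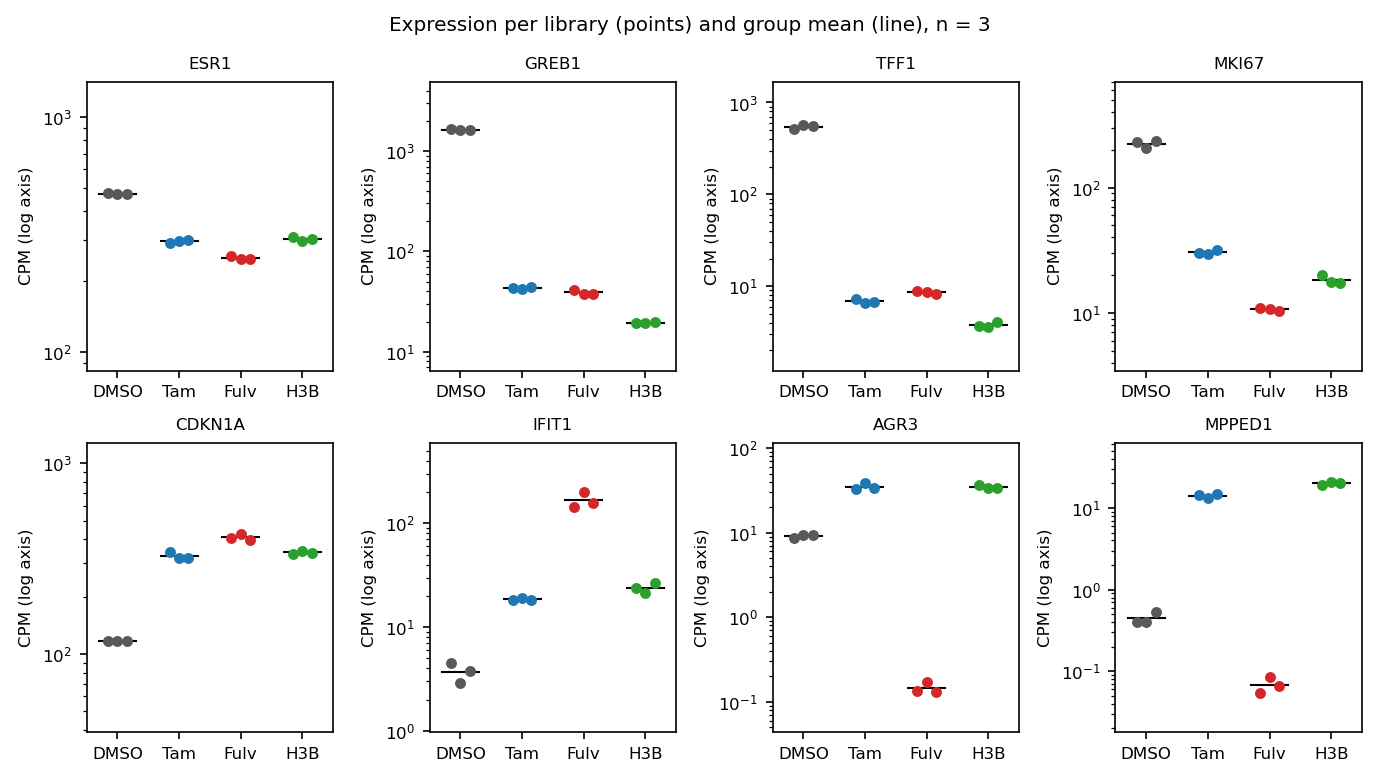
Expression of 8 genes per library in CPM on a log axis, with DMSO, tamoxifen (Tam), fulvestrant (Fulv) and H3B-5942 (H3B) along the x axis, points for the 3 libraries of each group and a line at their mean. GREB1 and TFF1 lie lowest in H3B-5942 and MKI67 lies lowest in fulvestrant, whereas AGR3 and MPPED1 stand above DMSO in tamoxifen and H3B-5942 and below it in fulvestrant.

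Tamoxifen against DMSO. Tamoxifen lowered most of the estrogen-induced genes and every measured gene of the cell division lists. TFF1, a secreted trefoil peptide and a classical estrogen target, was 79.4-fold lower (6.84 ± 0.310 against 545 ± 24.0 CPM, log2 fold change -6.31 ± 0.054, adjusted p = 4.74e-39). GREB1, another estrogen target, was 37.4-fold lower, at 43.2 ± 1.17 against 1618 ± 22.3 CPM. ELOVL2, an elongase of polyunsaturated fatty acids, and NPY1R, a neuropeptide Y receptor, fell by 16.4-fold and 20.8-fold. Of 40 estrogen-induced genes, 32 were lower and 6 higher (adjusted p = 8.81e-50, list test, and adjusted p = 2.09e-04 with an estimated correlation). The 6 that rose were CELSR2, FKBP4, RAPGEFL1, RARA, RET and SLC9A3R1, with log2 fold changes from 0.17 for SLC9A3R1 to 0.96 for RET, which encodes a receptor tyrosine kinase. The call of SLC9A3R1 was lost after removal of GC and length trends (adjusted p = 0.413). All 11 estrogen-repressed genes were higher (adjusted p = 5.47e-07), among them BMF, a BH3-only activator of apoptosis (1.90 ± 0.044), BTG2, an antiproliferative factor (0.91 ± 0.037), and BIK (2.55 ± 0.14).

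Among the cell division genes, all 25 mitosis genes were lower under tamoxifen (median log2 fold change -2.78, adjusted p = 7.02e-71). The estimated correlation of this list was 0.464, and the adjusted p with it was 0.00218. MKI67, the proliferation antigen Ki-67, fell from 223 ± 14.5 to 30.5 ± 1.18 CPM, and CDK1, the mitotic cyclin-dependent kinase, from 49.7 ± 4.02 to 5.13 ± 0.123 CPM. All 30 DNA replication genes tested were lower as well (median -1.75, adjusted p = 2.97e-50, and adjusted p = 0.00110 with an estimated correlation). They included RRM2, a ribonucleotide reductase subunit (-2.95 ± 0.058), TK1, thymidine kinase (-2.97 ± 0.070), and CCNA2, cyclin A2 (-2.98 ± 0.070). Of 16 growth arrest genes, 10 were higher and 3 lower (adjusted p = 1.81e-04, and adjusted p = 0.116 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, rose from 117 ± 0.295 to 326 ± 12.9 CPM and CDKN2B, p15, from 6.41 ± 0.872 to 27.9 ± 2.70 CPM, while CDKN2C, p18, had a log2 fold change of -2.04 ± 0.14. Of 16 p53 targets, 10 were higher and 4 lower (adjusted p = 0.00212, and adjusted p = 0.219 with an estimated correlation), with GDF15, a stress-induced cytokine, at 2.52 ± 0.068 and DDB2, a DNA damage binding protein, at -0.96 ± 0.054. In the BCL2 family 10 of 15 members were higher and 2 lower (adjusted p = 1.81e-04), with BBC3, the BH3-only protein PUMA, at 1.59 ± 0.053 and the survival gene BCL2 at -0.90 ± 0.040.

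Metabolic and stress lists moved in several directions under tamoxifen. Of 20 hypoxia and glycolysis genes, 16 were lower and 2 higher (adjusted p = 1.13e-16), and LDHA, lactate dehydrogenase A, fell from 905 ± 28.9 to 164 ± 1.84 CPM. The 2 that rose were ADM, adrenomedullin (1.01 ± 0.20), and SLC2A1, a glucose transporter (0.61 ± 0.040). Cholesterol synthesis genes were lower in 17 of 24 cases (adjusted p = 3.02e-04, and adjusted p = 0.0850 with an estimated correlation), with FDFT1, squalene synthase, at -1.17 ± 0.044 and DHCR7, the last enzyme of the pathway, at -0.82 ± 0.041. Fatty acid synthesis genes were lower in 7 and higher in 3 of 14 cases (adjusted p = 0.0435, and adjusted p = 0.250 with an estimated correlation). That call was lost without DMSO library 1 (0.0505), without tamoxifen library 2 (0.0521) and without fulvestrant library 3 (0.0506), and the median of -0.11 turned to 0.0068 on log2(TPM + 0.1) values. SCD, stearoyl-CoA desaturase, had a log2 fold change of -0.96 ± 0.042. Of 19 ER stress and ATF4 genes, 13 were higher and 5 lower (adjusted p = 1.34e-08), led by SLC7A11, the cystine transporter (2.85 ± 0.068), and DDIT3, the transcription factor CHOP (1.67 ± 0.050). Lysosome genes were higher in 16 and lower in 3 of 22 cases (adjusted p = 0.00204), with PSAP, prosaposin, at 1.09 ± 0.037 and GLA, alpha-galactosidase A, at -1.97 ± 0.070. Ribosome biogenesis genes were lower in 13 and higher in 4 of 22 cases, which did not pass the list test (adjusted p = 0.153). That list passed once each library's trend with GC content and length was removed (adjusted p = 0.00713).

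Of 27 interferon response genes, 18 were higher under tamoxifen and 3 lower (adjusted p = 6.87e-05, and adjusted p = 0.361 with an estimated correlation). IRF7, a transcription factor of the interferon response, rose from 9.28 ± 0.573 to 22.6 ± 0.425 CPM, and the 3 that fell were HERC5, HERC6 and IFI44. Drug metabolism genes were higher in 7 and lower in 5 of 13 cases (adjusted p = 0.0397, and adjusted p = 0.183 with an estimated correlation). This call was lost without fulvestrant library 3 (0.0521) and after removal of GC and length trends (0.143). CYP1A1 and AHRR, both targets of the aryl hydrocarbon receptor, stood at 3.27 ± 0.11 and 1.99 ± 0.061. Growth factor signalling genes went both ways, 12 higher and 7 lower of 21 (adjusted p = 0.790), with IGFBP4, an IGF binding protein, at -2.44 ± 0.038 and IGFBP3 at 4.11 ± 0.083. Luminal identity genes did so too, 9 higher and 8 lower of 20 (adjusted p = 0.213, 10 higher when adjusted over the list alone). Their median was 0.027, -0.14 after removal of GC and length trends, and their mean -0.22, with TFF3, a trefoil peptide, at -5.10 ± 0.11 and AGR3, a protein disulfide isomerase family member, at 1.93 ± 0.066.

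Markers of other cell types were also followed. Basal epithelial markers were higher in 10 and lower in 2 of 15 cases (adjusted p = 5.80e-04), with KRT15 going from 11.3 ± 0.982 to 49.1 ± 3.52 CPM and LAMC2, a laminin subunit, from 2.21 ± 0.337 to 8.39 ± 0.455 CPM. Of 14 blood cell markers 6 were expressed enough to test, and 4 were higher at low levels (adjusted p = 0.389), such as CD68 at 8.41 ± 0.122 against 5.28 ± 0.370 CPM. Of 14 stromal and vessel markers 7 were tested, 3 higher and 1 lower (adjusted p = 0.772), and COL1A1, a fibrillar collagen chain, stood at 31.7 ± 2.57 against 36.7 ± 1.39 CPM. Genes encoded by the mitochondrial genome were lower in 10 of 13 cases (adjusted p = 0.00204, and adjusted p = 0.345 with an estimated correlation), a call lost once GC and length trends were removed (0.106), with MT-CO2, a cytochrome oxidase subunit, at -0.75 ± 0.044.

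Beyond the lists, the largest rises under tamoxifen, among called genes with a mean of at least 5 CPM in the higher group and libraries that do not overlap, were those of MPPED1 (0.443 to 14.2 ± 0.764 CPM), NT5E, the ecto-nucleotidase CD73 (0.774 to 20.6 ± 1.49 CPM), ADCY5, an adenylyl cyclase (1.23 to 32.2 ± 0.402 CPM), ACHE, acetylcholinesterase (1.01 to 24.3 ± 1.30 CPM), KRT13 (2.08 to 49.0 ± 4.72 CPM) and the immunoglobulin heavy chain gene IGHG4 (0.763 to 15.7 ± 2.09 CPM). IGHG4 shares near-identical sequence with its neighbours, so its estimate is uncertain. The largest falls within these limits, beside TFF1, GREB1 and TFF3, were those of GRPR, the gastrin-releasing peptide receptor (24.2 to 0.186 CPM), the cytokine IL20 (21.8 to 0.271 CPM) and IGSF1 (16.9 to 0.602 CPM). For GRPR, with 3 counts in a tamoxifen library, DMSO to tamoxifen gave a ratio of pooled CPM of 126 (95% counting interval 81.7 to 207). Over 15753 genes tested, 5116 were higher and 5307 lower, of which 1134 and 826 changed at least 2-fold. On log2(TPM + 1) values tested with limma-trend the split was 5919 higher and 3371 lower. When a change of more than 1.5-fold was tested, 1435 were higher and 1137 lower.

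**Figure D2:**
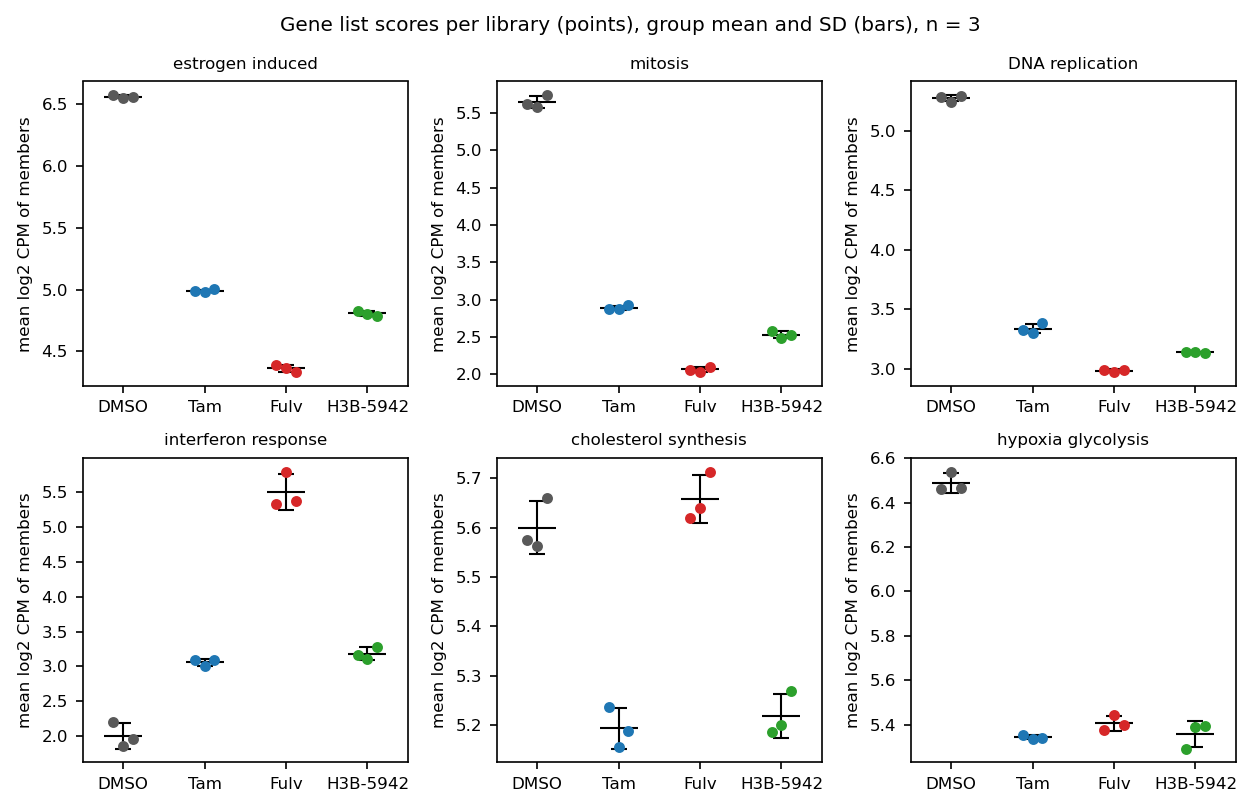
Mean log2 CPM of the members of 6 gene lists (y axis) in each library, with points for the 3 libraries of DMSO, tamoxifen (Tam), fulvestrant (Fulv) and H3B-5942, and bars for group mean and SD. The interferon response score was 2.001 ± 0.18 in DMSO, 3.06 ± 0.051 in tamoxifen, 5.50 ± 0.26 in fulvestrant and 3.18 ± 0.091 in H3B-5942, and the mitosis score was 5.64 ± 0.081, 2.89 ± 0.030, 2.07 ± 0.036 and 2.53 ± 0.052 in the same order.

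Fulvestrant against DMSO. Fulvestrant lowered nearly all estrogen-induced genes, lowered every tested gene of the mitosis and DNA replication lists and raised every member of the interferon response list. ELOVL2 fell from 416 ± 12.6 to 4.404 ± 0.184 CPM (94.1-fold, log2 fold change -6.56 ± 0.053, adjusted p = 1.22e-39), GREB1 from 1618 ± 22.3 to 39.0 ± 2.11 CPM and TFF1 from 545 ± 24.0 to 8.66 ± 0.326 CPM. PGR, which encodes the progesterone receptor, had a log2 fold change of -5.01 ± 0.058, and IGFBP4 one of -4.37 ± 0.043. In all, 38 of 40 estrogen-induced genes were lower (adjusted p = 1.88e-65, and adjusted p = 3.53e-04 with an estimated correlation). PRSS23 (0.050 ± 0.054) and RARA (0.012 ± 0.044) were not called. Both were called higher on log2(TPM + 1) values (PRSS23 at 0.26 and RARA at 0.22), and after removal of GC and length trends PRSS23 was called higher at 0.18 and RARA lower at -0.070. Estrogen-repressed genes were higher in 10 of 11 cases (adjusted p = 9.52e-06), the exception being ERBB3, a receptor of the EGFR family (-0.41 ± 0.036).

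All 27 interferon response genes were higher under fulvestrant (median log2 fold change 3.48, adjusted p = 7.71e-28, and adjusted p = 0.0463 with an estimated correlation). OAS1, an oligoadenylate synthetase that senses double-stranded RNA, rose from 1.46 ± 0.788 to 87.9 ± 15.7 CPM and IFIT1, an interferon-induced RNA binding protein, from 3.72 ± 0.789 to 167 ± 28.1 CPM. IRF7 and CMPK2 had log2 fold changes of 2.75 ± 0.061 and 4.999 ± 0.21. The 25 mitosis genes were all lower (median -3.59, adjusted p = 2.22e-62), MKI67 falling to 10.7 ± 0.294 CPM and CDK1 to 2.16 ± 0.213 CPM, and so were the 30 DNA replication genes (median -2.11, adjusted p = 2.16e-41), MCM2, a subunit of the replicative helicase, at -2.36 ± 0.051. With an estimated correlation the adjusted p was 0.00408 for both the mitosis and the DNA replication list. Growth arrest genes were higher in 9 and lower in 5 of 16 cases (adjusted p = 2.08e-04, and adjusted p = 0.116 with an estimated correlation), with CDKN1A at 1.81 ± 0.039 and the transcription factor KLF4 at 2.58 ± 0.069. Of 16 p53 targets 11 were higher and 4 lower (adjusted p = 3.48e-04, and adjusted p = 0.136 with an estimated correlation). Of 15 BCL2 family members 9 were higher and 2 lower (adjusted p = 0.0205, and adjusted p = 0.0597 with an estimated correlation), BCL2 itself at -1.50 ± 0.041.

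Stress and lysosome genes were mostly higher under fulvestrant. Of 19 ER stress and ATF4 genes 13 rose and 4 fell (adjusted p = 5.04e-11), with SLC7A11 at 4.01 ± 0.065 and HSPA5, the chaperone BiP, at 1.30 ± 0.039. Of 22 lysosome genes 18 rose and 3 fell (adjusted p = 2.26e-05), and SQSTM1, the autophagy receptor p62, went from 492 ± 14.6 to 2163 ± 48.5 CPM. Drug metabolism genes rose in 8 of 13 cases (adjusted p = 2.02e-05), with NQO1, a quinone reductase, at 1.74 ± 0.036 and ABCG2, a drug efflux transporter, at 1.68 ± 0.060. Hypoxia and glycolysis genes fell in 16 and rose in 4 of 20 cases (adjusted p = 1.07e-09), with LDHA at -2.27 ± 0.038. Cholesterol synthesis genes were split, 13 higher and 8 lower of 24 (adjusted p = 0.715): LDLR, the LDL receptor, was at 0.82 ± 0.039 and CYP51A1 at 0.86 ± 0.042, but TM7SF2 was at -0.93 ± 0.046 and FDFT1 at -0.80 ± 0.042. Fatty acid synthesis genes were split too, 8 higher and 5 lower of 14 (adjusted p = 0.191), their median of 0.15 and mean of -0.070 differing in sign and the median turning to -0.027 after removal of GC and length trends. Ribosome biogenesis genes were higher in 10 and lower in 5 of 22 cases (adjusted p = 0.835).

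Among growth factor genes, 11 were higher and 9 lower of 21 (adjusted p = 0.542). The median of 0.15 was positive, although the list test pointed down and the median became -0.012 after removal of GC and length trends. IGF1R, the IGF1 receptor, was at -2.12 ± 0.037 and FGFR4, a fibroblast growth factor receptor, at 1.52 ± 0.056. Luminal identity genes were lower in 12 and higher in 7 of 20 cases (adjusted p = 7.60e-05, and adjusted p = 0.0823 with an estimated correlation), and AGR2, a protein disulfide isomerase, fell from 262 ± 9.68 to 17.2 ± 0.976 CPM. Basal markers were higher in 12 and lower in 1 of 15 cases (adjusted p = 4.42e-04), with KRT17 at 14.6 ± 0.525 against 1.33 ± 0.300 CPM, an estimate that its pseudogenes make uncertain. Of 6 blood cell markers tested 4 were higher and 1 lower (adjusted p = 0.367), CD68 at 12.1 ± 0.923 CPM. Of 7 stromal markers 4 were higher and 2 lower (adjusted p = 0.552), COL1A1 at 55.0 ± 2.65 CPM. Mitochondrially encoded genes were lower in 11 of 13 cases (adjusted p = 0.0204, and adjusted p = 0.465 with an estimated correlation), a call lost after removal of GC and length trends (0.417).

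Among genes of at least 5 CPM as above, the largest rises under fulvestrant, beside OAS1 and IFIT1, were those of CGA, the alpha subunit of the glycoprotein hormones (0.130 to 10.4 ± 2.15 CPM), KLHDC7B (1.24 to 76.4 ± 14.0 CPM), LCN2, lipocalin 2 (0.385 to 20.8 ± 2.78 CPM), and ADCY5 (1.23 to 52.0 ± 3.86 CPM). CGA had 3 counts in a DMSO library, and its ratio of pooled CPM was 75.9 (95% counting interval 49.9 to 122). The largest falls by the same rule, beside ELOVL2 and TFF1, were those of SLC6A14, an amino acid transporter (310.0 ± 13.6 to 2.27 ± 0.217 CPM), SULF1, a heparan sulfate sulfatase (332 ± 14.95 to 4.19 ± 0.240 CPM), IL20 (21.8 to 0.233 CPM) and GRPR (24.2 to 0.0420 CPM, ratio of DMSO to fulvestrant 570.5 with a 95% counting interval of 244 to 1758). Over 15753 genes, 5589 were higher and 5908 lower, 1420 and 1290 of them at least 2-fold. With limma-trend on log2(TPM + 1) values the split was 7110 higher and 3527 lower. Testing for a change of more than 1.5-fold left 1927 higher and 1784 lower.

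H3B-5942 against DMSO. H3B-5942 lowered estrogen-induced genes and every tested gene of the cell division lists. TFF1 fell 144-fold, from 545 ± 24.0 to 3.79 ± 0.227 CPM (log2 fold change -7.17 ± 0.057, adjusted p = 4.02e-40), and GREB1 fell 83.3-fold, from 1618 ± 22.3 to 19.4 ± 0.216 CPM. Of 40 estrogen-induced genes 34 were lower (adjusted p = 2.58e-56, and adjusted p = 5.04e-05 with an estimated correlation). Another 5 were higher, namely CELSR2, FKBP4, RAPGEFL1, RARA and RET. Their log2 fold changes ran from 0.091 ± 0.036 for FKBP4, an HSP90 co-chaperone, to 0.61 ± 0.048 for RET. The call of FKBP4 was lost without DMSO library 1 or 2 or H3B-5942 library 1 or 2 (adjusted p from 0.0769 to 0.102), with no filter (0.0692) and after removal of GC and length trends (0.285). Estrogen-repressed genes were higher in 10 of 11 cases (adjusted p = 2.50e-06), with BMF at 1.92 ± 0.043 and IL1R1, the interleukin 1 receptor, at 2.15 ± 0.13. All 25 mitosis genes (median -3.04, adjusted p = 6.09e-78) and all 30 DNA replication genes tested (median -1.85, adjusted p = 6.02e-54) were lower, with MKI67 at 18.4 ± 1.46 CPM, CDC20, an activator of the anaphase-promoting complex, at -3.25 ± 0.064, TK1 at -3.65 ± 0.073 and CDT1, a replication licensing factor, at -2.61 ± 0.060. With an estimated correlation the adjusted p was 0.00155 for the mitosis list and 8.64e-04 for the DNA replication list.

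Growth arrest genes were higher in 10 and lower in 3 of 16 cases under H3B-5942 (adjusted p = 1.03e-04, and adjusted p = 0.114 with an estimated correlation), with CDKN1A at 341 ± 6.93 CPM and GADD45A at 1.93 ± 0.064. Of 16 p53 targets 11 rose and 3 fell (adjusted p = 4.60e-04, and adjusted p = 0.146 with an estimated correlation). Of 15 BCL2 family members 10 rose and 3 fell (adjusted p = 2.17e-04), with HRK at 2.28 ± 0.088 and BAK1, an effector of apoptosis, at 0.88 ± 0.046. Interferon response genes were higher in 18 and lower in 1 of 27 cases (3 lower when adjusted over the list alone, adjusted p = 1.38e-05, and adjusted p = 0.321 with an estimated correlation), with IRF9 at 1.55 ± 0.082 and IFI44 the gene that fell. ER stress and ATF4 genes were higher in 12 and lower in 5 of 19 cases (adjusted p = 1.75e-09), SLC7A11 at 3.24 ± 0.066 and ASNS, asparagine synthetase, at 1.51 ± 0.046. Lysosome genes were higher in 16 and lower in 3 of 22 cases (adjusted p = 0.00135), PSAP at 1.11 ± 0.037. Hypoxia and glycolysis genes were lower in 15 (16 adjusted over the list alone) and higher in 3 of 20 cases (adjusted p = 8.39e-15), with BNIP3, a mitophagy receptor, at -2.004 ± 0.042 and NDRG1 at -2.10 ± 0.049.

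Cholesterol synthesis genes were lower in 17 and higher in 3 of 24 cases under H3B-5942 (adjusted p = 7.29e-04, and adjusted p = 0.131 with an estimated correlation), with FDFT1 at -1.14 ± 0.043 and EBP at -1.14 ± 0.057. Fatty acid synthesis genes were lower in 9 (10 adjusted over the list alone) and higher in 3 of 14 cases (adjusted p = 0.0378, and adjusted p = 0.248 with an estimated correlation), with ELOVL6, a fatty acid elongase, at -1.31 ± 0.055. Drug metabolism genes were higher in 7 and lower in 2 of 13 cases (adjusted p = 0.0208, and adjusted p = 0.136 with an estimated correlation), a call lost after removal of GC and length trends (0.0636), with CYP1A1 at 3.45 ± 0.11. Growth factor genes were higher in 10 and lower in 7 of 21 cases (adjusted p = 0.743), with IRS1, an insulin receptor substrate, at -0.71 ± 0.036. Their median of 0.050 was above 0 although the list test pointed down, and it was -0.13 after removal of GC and length trends. Luminal identity genes were lower in 10 and higher in 7 of 20 cases, short of passing (adjusted p = 0.0519), but passed without DMSO library 2 (0.0457), DMSO library 3 (0.0324) or tamoxifen library 2 (0.0367). Their median of -0.086 was 0.029 on log2(TPM + 1) values, with XBP1, a transcription factor of the secretory pathway, at -1.44 ± 0.036. Basal markers were higher in 10 and lower in 2 of 15 cases (adjusted p = 7.01e-04), LAMC2 at 9.54 ± 0.783 CPM. Of 6 blood cell markers 4 were higher (adjusted p = 0.333), CD68 at 7.97 ± 0.0266 CPM. Of 7 stromal markers 3 were higher and 1 lower (2 adjusted over the list alone, adjusted p = 0.743), with COL1A1 at 31.7 ± 0.602 CPM. The stromal median of -0.15 and mean of 0.67 differed in sign, and the median was 0.031 on log2(TPM + 1) values. Ribosome biogenesis genes were lower in 13 and higher in 5 of 22 cases (adjusted p = 0.126, 0.0118 after removal of GC and length trends). Mitochondrially encoded genes were lower in 10 of 13 cases (adjusted p = 0.00402, and adjusted p = 0.342 with an estimated correlation).

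Within the same limit of 5 CPM, the largest rises under H3B-5942 were those of MPPED1 (0.443 to 19.98 ± 0.964 CPM), NT5E (21.1 ± 1.43 CPM), ACHE (25.3 ± 0.720 CPM), ADCY5 (27.001 ± 0.226 CPM), TGFB2, a TGF-beta ligand (8.55 to 170.1 ± 3.80 CPM), and IGFBP3 (2.43 to 46.4 ± 2.05 CPM). The largest falls there, beside TFF1 and GREB1, were those of TFF3 (0.753 ± 0.168 CPM), IGSF1 (0.570 ± 0.292 CPM), IL20 (0.182 CPM, ratio of DMSO to H3B-5942 126 with a 95% counting interval of 83.1 to 201) and GRPR (0.0845 CPM, ratio 279.9 with an interval of 156 to 561). Over 15753 genes, 5240 were higher and 5488 lower, 1202 and 907 of them at least 2-fold. With limma-trend on log2(TPM + 1) values the split was 5929 higher and 3594 lower. Testing for a change of more than 1.5-fold left 1519 higher and 1290 lower.

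Overlap of the responses. Tamoxifen and H3B-5942 moved 9060 genes in the same direction and 55 in opposite directions, tamoxifen and fulvestrant 8380 and 558, and fulvestrant and H3B-5942 8600 and 506. Independent lists of these sizes would share 3551, 3805 and 3917 genes in the same direction. Over the 3 comparisons, 3758 genes were higher and 3939 lower under all compounds. Across genes, which are not independent replicates, Pearson's r of log2 fold changes was 0.93 for tamoxifen and H3B-5942 (Spearman's rho 0.91), 0.81 (0.78) for tamoxifen and fulvestrant and 0.83 (0.79) for fulvestrant and H3B-5942. All 3 comparisons use the same DMSO libraries, and 20 simulations of unchanged groups gave mean r of 0.43, 0.42 and 0.44 and a mean of 0.05, 0.05 and 0 genes called in the same direction. The covariances were 0.68, 0.70 and 0.77 against 0.017 in each simulation set. Of these, 0.66, 0.68 and 0.75 lay above what the spread between libraries adds through shared controls. A deviation common to all DMSO libraries was not simulated, and no choice among these libraries removes it. With another DMSO library for each compound, a form chosen after seeing the data, mean r of log2 CPM differences over the 6 assignments was 0.88 (0.88 to 0.89), 0.76 (0.76 to 0.77) and 0.78 (0.77 to 0.79), against simulated means of -0.00032, 0.00093 and 0.00073. With 1 DMSO library for both it was 0.95, 0.82 and 0.84, against simulated means of 0.71, 0.70 and 0.72. On the TPM scale the median log2 fold change of all genes was not 0. It was 0.073 for tamoxifen, 0.12 for fulvestrant and 0.073 for H3B-5942 with a pseudocount of 1, and 0.10, 0.17 and 0.10 with a pseudocount of 0.1, so the TPM splits are to be read relative to these shifts.

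**Figure D3:**
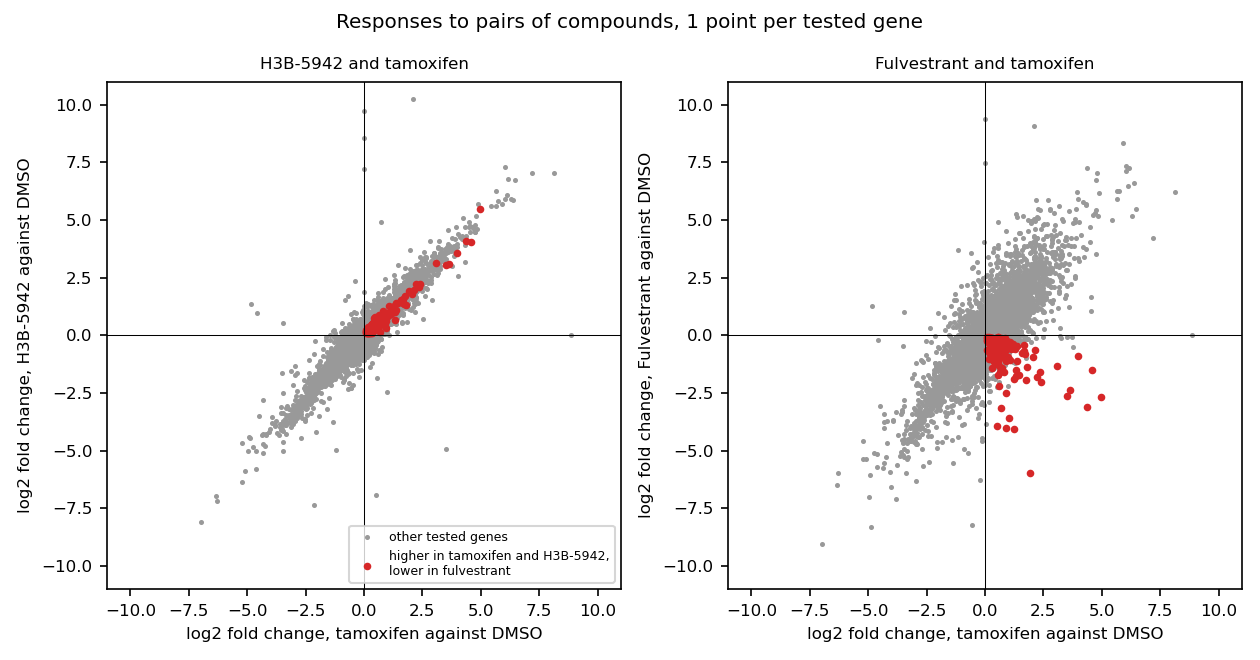
Log2 fold change against DMSO of H3B-5942 (left, y axis) and of fulvestrant (right, y axis) against that of tamoxifen (x axes), 1 grey point per tested gene, with the 178 genes called higher in tamoxifen and H3B-5942 and lower in fulvestrant in red. Pearson's r across genes is 0.93 on the left and 0.81 on the right, and the points far from the diagonal include genes with 0 counts in a group, whose fitted values are no bound.

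A set of 178 genes was higher under tamoxifen and H3B-5942 and lower under fulvestrant, and 176 genes had the reverse pattern. In all 178, fulvestrant was also called below tamoxifen and below H3B-5942 directly, which their selection by opposite calls against DMSO all but fixed in advance. Of the 178, 16 changed at least 2-fold in each comparison. They were chosen for description after their values were seen and comprise MPPED1, AGR3, IGHG4, IGHG2, KRT13, IGHE, SERPINA1, CD22, TGM2, KIF12, MAG, COL27A1, NKAIN1, ASTL, CLIC3 and SLC47A1. AGR3 stood at 9.10 ± 0.443 CPM in DMSO, 34.7 ± 3.11 in tamoxifen, 34.8 ± 1.73 in H3B-5942 and 0.146 ± 0.0231 in fulvestrant. SERPINA1, alpha-1 antitrypsin, stood at 15.2 ± 0.688, 36.1 ± 0.562, 31.4 ± 1.22 and 0.894 ± 0.0380 CPM, and TGM2, a transglutaminase, at 1.64 ± 0.282, 8.53 ± 0.537, 7.65 ± 0.408 and 0.397 ± 0.0560 CPM in the same order. Of the reverse set, 3 genes changed at least 2-fold in each comparison, SLC22A4, BTN3A3 and PDE4B, also named after their values were seen.

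H3B-5942 against tamoxifen. Estrogen-induced genes were lower as a list under H3B-5942 than under tamoxifen. So were the cell division lists at the preset correlation, but not with an estimated one. GREB1 stood at 19.4 ± 0.216 against 43.2 ± 1.17 CPM (log2 fold change -1.15 ± 0.048, 95% interval -1.25 to -1.06, adjusted p = 7.41e-18), IGFBP4 at 36.1 ± 1.197 against 72.4 ± 1.28 CPM (-1.003 ± 0.041) and TFF1 at 3.79 ± 0.227 against 6.84 ± 0.310 CPM (-0.86 ± 0.084). Of 40 estrogen-induced genes 16 were lower and 1, BCL2, higher (17 lower adjusted over the list alone, median -0.10, adjusted p = 2.39e-14). Of 25 mitosis genes 17 were lower (20 adjusted over the list alone, median -0.34, adjusted p = 2.61e-13, and adjusted p = 0.117 with an estimated correlation), with MKI67 at -0.73 ± 0.059 and TOP2A, topoisomerase II alpha, at -0.54 ± 0.071. That number was 11 without H3B-5942 library 3. Of 30 DNA replication genes 13 were lower (14 adjusted over the list alone, adjusted p = 3.22e-05, and adjusted p = 0.117 with an estimated correlation), with TK1 at -0.68 ± 0.093, and 7 were lower without tamoxifen library 3 and 6 without H3B-5942 library 1. Luminal identity genes were lower in 9 of 20 cases (adjusted p = 0.00388, and adjusted p = 0.312 with an estimated correlation), with MLPH at -0.19 ± 0.037, and in 5 without H3B-5942 library 1.

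The growth factor, ER stress, p53 and interferon response lists also passed the test between H3B-5942 and tamoxifen. Growth factor genes were lower in 5 and higher in 3 of 21 cases (5 higher adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.312 with an estimated correlation), a call lost without H3B-5942 library 2 (0.0777) and after removal of GC and length trends (0.506). ER stress and ATF4 genes were higher in 6 and lower in 1 of 19 cases (8 higher adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.312 with an estimated correlation), lost without H3B-5942 library 2 (0.112), with SLC7A11 at 0.38 ± 0.054. For p53 targets 6 were higher and 1 lower of 16 (7 higher adjusted over the list alone, adjusted p = 0.0169, and adjusted p = 0.554 with an estimated correlation), a call lost without tamoxifen library 3 (0.195) or H3B-5942 library 2 (0.142). The interferon response list passed its test pointing up (median 0.12, adjusted p = 0.0479, and adjusted p = 0.851 with an estimated correlation), although the 1 member called, IRF7, was lower at -0.18 ± 0.062 and not called when adjusted over the list alone. The call of IRF7 was lost without any 1 of the tamoxifen or H3B-5942 libraries (adjusted p from 0.0552 to 0.164), with limma-voom (0.0723), library totals (0.0634), effective lengths (0.0786) and both TPM forms (0.103 each), and its log2 fold change turned to 0.070 after removal of GC and length trends. The call of the list was lost without tamoxifen library 2 (0.173), fulvestrant library 3 (0.0594) or H3B-5942 library 3 (0.269), and with library totals in place of TMM (0.0681). As mean log2 CPM of the members, H3B-5942 minus tamoxifen was 0.12 (95% interval -0.19 to 0.43) for this list, 0.025 (95% interval -0.064 to 0.11) for cholesterol synthesis, 0.015 (95% interval -0.060 to 0.090) for hypoxia and glycolysis and 0.031 (95% interval -0.0042 to 0.065) for lysosome genes. For the latter 3 lists the tests did not pass (adjusted p = 0.787, 0.763 and 0.507). Nor did they for estrogen-repressed genes (2 higher, 2 lower), growth arrest (3 and 1, 5 and 2 adjusted over the list alone), fatty acid synthesis (3 and 3), ribosome biogenesis (2 and 4), basal markers (1 and 2) or the BCL2 family (3 and 4, 4 higher adjusted over the list alone), with adjusted p from 0.306 to 0.912. The BCL2 family passed after removal of GC and length trends (0.00919). Of drug metabolism genes 2 were higher (1 adjusted over the list alone, adjusted p = 0.312), and of mitochondrially encoded genes 1, MT-CO2, was lower at -0.15 ± 0.043 (adjusted p = 0.912 for the list). The call of MT-CO2 was lost without tamoxifen library 3, H3B-5942 library 1 or H3B-5942 library 3 (adjusted p from 0.0534 to 0.0553) and on log2(TPM + 1) (0.0715) and log2(TPM + 0.1) values (0.0615), and the list passed and pointed down after removal of GC and length trends (0.0415).

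With clone and reading frame names left out, the largest rises of H3B-5942 over tamoxifen among called genes of at least 5 CPM in the higher group were those of TM6SF1 (0.56 ± 0.12), HBEGF, an EGFR ligand (0.50 ± 0.13), MPPED1 (0.49 ± 0.071), LSMEM1 (0.48 ± 0.078) and ULBP1, an NKG2D ligand (0.48 ± 0.11). Beside GREB1 and IGFBP4, the largest falls among such genes were those of LRRC26 (-0.86 ± 0.11), POTEF (-0.95 ± 0.12) and RSC1A1 (-0.86 ± 0.25), the last 2 being uncertain because POTEF has near-identical relatives and RSC1A1 lies within another gene. RSC1A1 lost its call without DMSO library 2, tamoxifen library 3, fulvestrant library 3 or any 1 of the H3B-5942 libraries (adjusted p from 0.0520 to 0.104), and with no filter (0.0546) or a replicate block (0.0889). LSMEM1 lost its call with effective lengths as offsets (log2 fold change 0.24, adjusted p = 0.198) and on log2(TPM + 1) (0.23, 0.239) and log2(TPM + 0.1) values (0.24, 0.285), the last of which also ended the calls of HBEGF (0.0747) and MPPED1 (0.0851). Of 15753 genes 1340 were higher and 1925 lower, with a median size of 0.21 on the log2 scale, and 13 and 19 changed at least 2-fold. When a change of more than 1.5-fold was tested, 1 was higher and 3 lower. These were GREB1, IGFBP4 and, named after their values were seen, SFT2D3, counted in tamoxifen at 1.39 ± 0.586 CPM and at 0 in every other library, and RP11-343C2.12, counted in H3B-5942 at 1.09 ± 0.101 CPM and at 0 elsewhere. A count of 0 allows up to 0.0483 to 0.102 CPM in these libraries, for counting error only. The bound leaves out how the estimation divides reads between similar or overlapping genes. Such sharing was not tested for SFT2D3 or RP11-343C2.12, so a 0 may not mean absence. The numbers depended on single libraries and on scaling: the higher count was 648 without tamoxifen library 1, 657 without tamoxifen library 3, 661 without H3B-5942 library 1 and 672 without H3B-5942 library 3, and the lower count 1165 without H3B-5942 library 1. Removal of GC and length trends gave 686 and 1108, effective lengths as offsets 547 and 1133, and limma-trend on log2(TPM + 1) values 384 higher and 966 lower.

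H3B-5942 against fulvestrant. Interferon response genes were lower and most estrogen-induced genes higher under H3B-5942 than under fulvestrant. All 27 interferon response genes were lower (median -2.46, adjusted p = 2.05e-52), including IRF7 (19.999 ± 0.491 against 62.8 ± 5.48 CPM, log2 fold change -1.65 ± 0.057, adjusted p = 7.14e-22), the ubiquitin ligase HERC6 (-3.15 ± 0.093), OAS3 (-3.20 ± 0.17) and UBE2L6, an ISG15-conjugating enzyme (-3.16 ± 0.32). The estimated correlation of this list was 0.704, and the adjusted p with it was 0.0180. Of 40 estrogen-induced genes 23 were higher and 12 lower (adjusted p = 1.46e-14), with RAPGEFL1 at 2.97 ± 0.061 and STC2, stanniocalcin 2, at 1.84 ± 0.044, but GREB1 at -1.003 ± 0.048 and TFF1 at -1.19 ± 0.079. Mitosis genes were higher in 18 and lower in 2 of 25 cases (19 and 3 adjusted over the list alone, adjusted p = 0.00284, and adjusted p = 0.402 with an estimated correlation), with MKI67 at 0.79 ± 0.067. DNA replication genes were higher in 17 and lower in 5 of 30 cases (adjusted p = 0.178, and 0.0390 after removal of GC and length trends).

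Lipid synthesis genes were lower under H3B-5942 than under fulvestrant. Of 24 cholesterol synthesis genes 18 were lower and 2 higher (19 lower adjusted over the list alone, adjusted p = 1.60e-09), with LDLR at -1.24 ± 0.040 and LSS, lanosterol synthase, at -0.95 ± 0.043. Of 14 fatty acid synthesis genes 11 were lower and 1 higher (adjusted p = 3.73e-09), with SREBF1, a transcription factor of lipid synthesis, at -1.30 ± 0.040. Drug metabolism genes were lower in 8 and higher in 3 of 13 cases (adjusted p = 3.25e-06), NQO1 at -1.44 ± 0.035. Lysosome genes were lower in 16 and higher in 2 of 22 cases (adjusted p = 0.00324), SQSTM1 at -1.02 ± 0.038. ER stress genes (13 lower and 2 higher of 19, adjusted p = 0.00293, and adjusted p = 0.132 with an estimated correlation) and ribosome biogenesis genes (18 lower and 3 higher of 22, adjusted p = 0.00737, and adjusted p = 0.125 with an estimated correlation) were lower too. Luminal identity genes were higher in 6 and lower in 7 of 20 cases, with a test that pointed up (mean log2 fold change 0.51, adjusted p = 1.32e-04, and adjusted p = 0.125 with an estimated correlation). Their call was lost after removal of GC and length trends (0.323), and their median of 0.021 was -0.075 on log2(TPM + 1) values. AGR2 rose from 17.2 ± 0.976 to 368 ± 4.72 CPM between these groups. Basal markers were lower in 10 (11 adjusted over the list alone) and higher in 2 of 15 cases (adjusted p = 0.249, 0.0492 after removal of GC and length trends). Lists for estrogen-repressed genes (4 higher, 6 lower), growth arrest (4 and 6), p53 targets (4 and 9), hypoxia (6 and 10), growth factors (8 and 9, 9 higher adjusted over the list alone) and the BCL2 family (5 and 4, 5 lower adjusted over the list alone and 7 lower without fulvestrant library 3) did not pass (adjusted p from 0.185 to 0.572).

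From 5 CPM in the higher group upwards, the largest rises were those of MPPED1 (0.0683 to 19.98 ± 0.964 CPM, ratio 294 with a 95% counting interval of 149 to 683), AGR3 (0.146 to 34.8 ± 1.73 CPM), IGHG4 (0.0869 to 13.1 ± 0.716 CPM, ratio 155 with an interval of 84.0 to 323), KRT13 (5.56 ± 0.11) and IGHE (5.47 ± 0.16). IGHG4 and IGHE are uncertain because related genes share their reads. The largest falls above that level, beside OAS3, UBE2L6 and HERC6, were those of MAOB, monoamine oxidase B (-3.32 ± 0.085), and RFTN1 (-3.25 ± 0.072). Of 15753 genes 3937 were higher and 4295 lower, 440 and 438 at least 2-fold. With limma-trend on log2(TPM + 1) values the split was 2222 higher and 5241 lower. Testing for a change of more than 1.5-fold left 431 higher and 566 lower.

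Fulvestrant against tamoxifen. Fulvestrant gave higher interferon response and lipid synthesis genes and lower estrogen-induced genes than tamoxifen. The cell division lists were lower at the preset correlation, but not with an estimated one. All 27 interferon response genes were higher (median 2.57, adjusted p = 2.02e-52), HERC6 going from 3.74 ± 0.0559 to 41.5 ± 6.26 CPM and IFI44L from 18.4 ± 0.634 to 175 ± 34.2 CPM. The estimated correlation of this list was 0.702, and the adjusted p with it was 0.0174. Of 40 estrogen-induced genes 25 were lower and 8 higher (26 lower adjusted over the list alone, adjusted p = 8.31e-25), with RAPGEFL1 at -3.39 ± 0.061 and IGFBP4 at -1.92 ± 0.044, whereas AREG, an EGFR ligand, was at 1.42 ± 0.19. Of 25 mitosis genes 21 were lower and 1, AURKA, higher (adjusted p = 2.81e-08, and adjusted p = 0.114 with an estimated correlation), with MKI67 at -1.51 ± 0.065. Of 30 DNA replication genes 19 were lower and 3 higher (20 lower adjusted over the list alone, adjusted p = 0.00253, and adjusted p = 0.118 with an estimated correlation).

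Of 24 cholesterol synthesis genes 19 were higher and 2 lower (adjusted p = 3.52e-09), with LDLR at 1.30 ± 0.041 and CYP51A1 at 0.97 ± 0.043. Of 14 fatty acid synthesis genes 11 were higher and 1 lower (adjusted p = 4.78e-08), with ACSL3, an acyl-CoA synthetase, at 1.34 ± 0.041. Drug metabolism genes were higher in 8 of 13 cases (1 lower adjusted over the list alone, adjusted p = 5.73e-07), NQO1 at 1.48 ± 0.036, and lysosome genes in 15 of 22 (16 adjusted over the list alone) with 1 lower (adjusted p = 0.00122). Basal markers were higher in 11 and lower in 2 of 15 cases (adjusted p = 0.211, 0.0215 after removal of GC and length trends). Lists for estrogen-repressed genes (6 higher, 4 lower), growth arrest (7 and 3), hypoxia (10 and 6, 7 lower adjusted over the list alone) and the BCL2 family (5 and 6) did not pass (adjusted p from 0.1998 to 0.447). ER stress genes were higher in 11 and lower in 2 of 19 cases (adjusted p = 9.50e-05, and adjusted p = 0.0583 with an estimated correlation), DDIT3 at 1.01 ± 0.044. Ribosome biogenesis genes were higher in 17 (18 adjusted over the list alone) and lower in 3 of 22 cases (adjusted p = 0.0197, and adjusted p = 0.118 with an estimated correlation). Luminal identity genes were lower in 10 and higher in 4 of 20 cases (adjusted p = 5.73e-07, and adjusted p = 0.0540 with an estimated correlation), a call lost after removal of GC and length trends (0.0675). For p53 targets 8 of 16 were higher (adjusted p = 0.0368, and adjusted p = 0.363 with an estimated correlation), a call lost without tamoxifen library 3 (0.0693) or fulvestrant library 2 (0.0613). Growth factor genes went both ways, 11 higher and 8 lower of 21 (9 lower adjusted over the list alone). Their test pointed down (adjusted p = 0.0481, and adjusted p = 0.294 with an estimated correlation) against a median of 0.21, and the call was lost without DMSO library 2, without any 1 of the fulvestrant libraries and without any 1 of the H3B-5942 libraries (0.0610 to 0.113).

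At 5 CPM or more in the higher group, and beside HERC6 and IFI44L, the largest rises of fulvestrant over tamoxifen were those of MAOB (3.47 ± 0.090), UBE2L6 (3.40 ± 0.34) and OAS3 (3.25 ± 0.17). The largest falls among such genes were those of AGR3 (34.7 ± 3.11 to 0.146 CPM), MPPED1 (14.2 ± 0.764 to 0.0683 CPM, ratio of tamoxifen to fulvestrant 210.2 with a 95% counting interval of 106 to 488), IGHG4 (15.7 ± 2.09 to 0.0869 CPM, ratio 186 with an interval of 101 to 388), KRT13 (-6.07 ± 0.11) and IGHE (-6.03 ± 0.15). Of 15753 genes 4247 were higher and 4045 lower, 460 and 512 at least 2-fold. With limma-trend on log2(TPM + 1) values the split was 5082 higher and 2487 lower. Testing for a change of more than 1.5-fold left 548 higher and 553 lower.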

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

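Tests on a single library, interferon ligands, B cells, members without whole counts, the part changed 2-fold, partial agonism and separate preparation were chosen after the results had been seen. So were thinning for depth and the correction for GC and length trends, whose limits were set before their own outcomes. For B cells, the limit on light chains was added after the levels had been seen. Tests on blood cells and on members with whole counts had limits set before.

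The interferon response score was higher in fulvestrant than in tamoxifen by 2.44 on the log2 scale (95% interval 2.13 to 2.76), a difference between the responses to these compounds tested directly. Blood cells in the fulvestrant cultures would bring their abundant transcripts, but 1 of 5 blood cell genes reached 1 CPM there, PTPRC, at 4.27 CPM against 4.78 CPM in DMSO. A single deviating library would end the calls once left out, yet at least 27 members were called higher than in tamoxifen without any 1 of the 12 libraries. Transcripts of the interferon ligands IFNB1, IFNL1, IFNL2 and IFNL3 summed to 2.04 to 3.82 CPM in the fulvestrant libraries, where all 3 exceeded every other library (0.0322 to 0.395 CPM), so interferon made by these cultures may take part. Whether the compound or another property of these cultures raised the ligands stays open, as untested.

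Between groups, 178 genes moved in opposite directions, higher under tamoxifen and H3B-5942 and lower under fulvestrant. Direct tests between the compounds add little here, since the selection all but fixed their outcome. For B cells as the source of the immunoglobulin part, the limit set first was missed, since 3 of 7 B cell genes reached 1 CPM. Of these, PTPRC (4.21 to 4.88 CPM) and PAX5 (1.14 to 1.34 CPM) differed little between the 4 groups and did not follow the pattern. CD79A rose from 0.232 CPM in DMSO to 0.753 in tamoxifen and 1.09 in H3B-5942, but stood at 0.742 in fulvestrant too. CD22, a B cell gene outside those 7, moved with the pattern (log2 fold change 3.08 in tamoxifen, 3.15 in H3B-5942 and -1.34 in fulvestrant). By the limit added later, B cells are argued against by light chain counts of at most 2.44% of heavy chain counts in the tamoxifen and H3B-5942 libraries (22.6 to 45 against 1680 to 2646, and 29.2 to 55 light chain counts in DMSO). Reads shared between similar genes are argued against for 78 members by whole estimated counts within a tolerance of 0.01 in every library, and cannot be told apart from expression for the other 100, whose counts are split by estimation. After thinning to equal library totals 83.1% of members kept all 3 calls, short of the 90% set beforehand. Such a shortfall was to be read, as written beforehand, as unequal depth or scaling. That reading was set aside afterwards, because thinning also removes reads. All 178 kept their signs, but the thinned reads are a part of those that selected the genes, so this decides nothing. For the 30 that lost a call, the median log2 fold change went from 0.42 to 0.36 in tamoxifen (4 calls lost). It went from -0.18 to -0.17 in fulvestrant (19 lost) and from 0.39 to 0.37 in H3B-5942 (8 lost). The median SE grew from 0.064 to 0.071, 0.067 to 0.076 and 0.063 to 0.073. Depth therefore cannot be told apart from a small change for these 30. All 16 of the part changed at least 2-fold kept their calls, which the reuse of the same reads made likely. Partial agonism at estrogen targets cannot be told apart from a chance excess, since the 4 members that are estrogen-induced genes (CELSR2, FKBP4, RAPGEFL1 and RET) gave an odds ratio of 3.85 among the 5908 genes lower under fulvestrant (95% interval 0.98 to 10.965, Fisher's exact test, two-sided p = 0.0265), an interval that reaches below 1, and p was 0.0293 over the 105 members that kept every call without any 1 library but 0.104 over all members without FKBP4, whose call under H3B-5942 was lost without DMSO library 1 or 2 or H3B-5942 library 1 or 2, with no filter and after GC and length correction.

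The estrogen-induced score was lower in H3B-5942 than in tamoxifen, with a difference of -0.18 (95% interval -0.22 to -0.15), and the mitosis score too (-0.36, 95% interval -0.46 to -0.26), each tested directly, although the mitosis list lost its call with an estimated correlation (adjusted p = 0.117) and its 17 members called lower became 11 without H3B-5942 library 3. A trend with GC content or length as the whole cause is argued against by 14 estrogen-induced and 19 mitosis genes still called lower once it was removed. After thinning to equal totals 15 estrogen-induced and 14 mitosis genes were called lower, which met the limit set against unequal depth. The thinned reads are a part of those that gave the calls, so depth is not decided by this. Separate preparation of the H3B-5942 libraries cannot be told apart from the compound in this difference from tamoxifen, since 0 of the 3 are numbered within the run of the other 9, but as the whole cause of the differences from DMSO and fulvestrant it is argued against by correlations of at least 0.876 and 0.684 with those of tamoxifen, whose libraries lie in that run, with separate control libraries. A stronger action of H3B-5942 on estrogen targets at 100 nM stays open, as untested.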

How the results depend on the processing

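Thinned counts, GC and length correction, effective lengths and separate DMSO libraries were chosen after seeing the data. Of 342 values for counts of genes and correlations under other settings, 299 were taken as unchanged, 35 counts were smaller and 8 correlations moved. A count was taken as unchanged within 1.5 times. For a correlation the limit was the SD of r over 27 sets of single libraries (0.0080 to 0.011). On log2(TPM + 1) values, genes lower were 3371 (tamoxifen), 3527 (fulvestrant) and 3594 (H3B-5942) against DMSO and 2487 (fulvestrant against tamoxifen), and genes higher 2222 for H3B-5942 against fulvestrant. H3B-5942 against tamoxifen gave 384 and 966. With a pseudocount of 0.1 the same counts were 3346, 3525, 3572, 2488, 2222, 363 and 956. The cause was not tested. Testing for more than 1.5-fold gave, higher and lower, 1435 and 1137, 1927 and 1784, 1519 and 1290 against DMSO, 431 and 566 for H3B-5942 against fulvestrant, 1 and 3 against tamoxifen, and 548 and 553 for fulvestrant against tamoxifen, fewer by construction. For H3B-5942 against tamoxifen, GC and length correction gave 686 and 1108 and effective lengths 547 and 1133, and the cause was not tested. With each library left out in turn, its higher counts ran from 648 to 1658 and its lower from 1165 to 2244. Correlations of responses became 0.835 (tamoxifen and fulvestrant), 0.97497 (tamoxifen and H3B-5942) and 0.852 (fulvestrant and H3B-5942) over genes of at least 5 CPM, low levels being left out by construction. Over genes past the threshold in either they became 0.827 and 0.960 for the first 2 pairs, a selection on the change that can itself raise r. With another DMSO library for each compound they became 0.763, 0.884 and 0.784, lower by construction, as 1 control library is noisier and no longer shared. Replicate numbers do not pair the libraries, since same-number correlations of deviations ran from -0.069 to 0.030. With a replicate block every count of genes stayed within 1.5 times.

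Of 2394 list results, 2281 kept direction and side, 72 lost their call, 40 gained one and 1 reversed, mitochondrially encoded genes in H3B-5942 against tamoxifen after GC and length correction (adjusted p = 0.0415, cause not tested). An estimated correlation ended 37 calls and fry gained 30. Calls lost or gained by a left-out library or by scaling stand beside each list. The growth factor call between fulvestrant and tamoxifen was also lost with DESeq2 size factors (0.0502), library totals (0.0562) and GC and length correction (0.830), the tamoxifen fatty acid call with library totals (0.0511) and the H3B-5942 against tamoxifen interferon call with a replicate block (0.0514), while luminal genes under H3B-5942 passed with that block (0.0479). Of 3448 values for named genes, 3383 kept direction and side, 58 lost their call, 5 gained one and 2 reversed after GC and length correction, IRF7 in H3B-5942 against tamoxifen (0.070) and RARA in fulvestrant against DMSO (-0.070), the cause not tested. Depth limits some calls, since 85.4% to 94.2% were made again, in the same direction, after thinning to the lowest total. At the depth and spread of these libraries together, simulated 1.2-fold changes were recovered in 47.8% to 65.7% of cases, with far fewer genes changed than were called here.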

Other observations

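Gene groups outside the fixed lists were chosen after the interferon values had been seen. Of 12 tested antigen presentation genes, 9 were higher and 2 lower under tamoxifen than under DMSO (median log2 fold change 0.55), 12 higher under fulvestrant (median 1.44) and 9 higher and 2 lower under H3B-5942 (median 0.58). All 12 were lower in H3B-5942 than in fulvestrant and higher in fulvestrant than in tamoxifen, while the median log2 fold change of H3B-5942 against tamoxifen was -0.011. Of 11 nucleic acid sensing genes, 2 of which, DDX58 and IFIH1, are also in the interferon response list, 6 were higher and 1 lower under fulvestrant, 4 and 2 under tamoxifen, and 6 and 2 under H3B-5942. Between compounds, 7 of them were higher in fulvestrant than in tamoxifen (median 0.43), 7 were lower in H3B-5942 than in fulvestrant (median -0.14) and 3 were higher in H3B-5942 than in tamoxifen (median 0.16).

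Levels of the 3 genes lower under tamoxifen and H3B-5942 and higher under fulvestrant by at least 2-fold were as follows. SLC22A4, a carnitine and ergothioneine transporter, stood at 3.02 ± 0.275 CPM in DMSO, 1.21 ± 0.195 in tamoxifen, 1.45 ± 0.298 in H3B-5942 and 8.81 ± 0.402 in fulvestrant. BTN3A3, a butyrophilin, stood at 0.554 ± 0.268, 0.262 ± 0.112, 0.203 ± 0.0381 and 1.24 ± 0.225 CPM in the same order, and PDE4B, a cAMP phosphodiesterase, at 1.06 ± 0.353, 0.394 ± 0.114, 0.489 ± 0.241 and 2.55 ± 0.271 CPM. Transcripts of the interferon ligands were IFNB1 at 0.538, IFNL1 at 1.07, IFNL2 at 0.857 and IFNL3 at 0.364 CPM in fulvestrant, with IFNL2 and IFNL3 too alike in sequence to be told apart with confidence.

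For each comparison, the 6 libraries were split into 3 and 3 in all 10 ways, and the count of genes past the threshold was as large in 1 of the 10, the real split, with no split able to give a share under 0.1. With these 6 libraries alone, the real split gave 10269 genes for tamoxifen, 11249 for fulvestrant and 10846 for H3B-5942 against DMSO, and the highest other split gave 0 each time. Between compounds the real split gave 8174 for H3B-5942 against fulvestrant (highest other 1), 3694 for H3B-5942 against tamoxifen (highest other 0) and 7774 for fulvestrant against tamoxifen (highest other 0).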
